A study of Rattus norvegicus with 8 samples.

How the data were processed

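Total RNA from rat kidney was measured on 8 single-colour Agilent expression arrays. The rats were male, of the SD strain (Sprague-Dawley, an outbred laboratory strain) and 10 weeks old. Per the labels, 4 arrays carried control kidneys after 4 weeks of 0.5% methylcellulose, a vehicle, and 4 arrays carried kidneys after 4 weeks of a compound labelled APL at 150 mg/kg. APL is read here as allopurinol, the xanthine oxidase inhibitor that the series title names as the agent producing renal fibrosis. The title speaks of renal tubules while the tissue label of each sample says kidney, so how much of the sampled tissue was tubule is not given in the sources used here. The labels do not say in so many words that the 4 replicates of a group were separate animals. The p-values therefore measure the spread between these samples, whatever its source.

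RNA was extracted with a Qiagen column kit and labelled with Cy3, per the labels' protocols, which name a DNA labelling kit for this step. The arrays were scanned at 5 micrometres and read with Agilent Feature Extraction 10.5.1.1 under the protocol GE1_105_Dec08, per the file headers; the same software is named in the submitters' processing notes. The array design is 028282 and its header names the rat build rn4. The deposited scanner files hold, for every spot, linear intensity values: the median intensity of the spot, the median intensity of its local background, and a processed signal from which Feature Extraction had already removed background and spatial trends, per the file headers. They also hold flags for spots well above background, saturated spots and non-uniform spots. A further deposited table of the whole series holds the authors' values on a log2 scale. Set against the scanner values, that table is close to log2 of the processed signal minus the array's 75th percentile, centred for each probe on its median over the 8 arrays. Rebuilt so without a floor, 93.7% of the values lay within 0.01 of the table, with correlations of 0.9992 to 0.9997 per array. With the floor used here 82.8% did, with correlations of 0.969 to 0.996. The medians of its columns were 0.0334, 0.0654, 0.0759 and 0.00539 for control replicates 1 to 4 and -0.0714, 0.0190, -0.135 and -0.0434 for allopurinol replicates 1 to 4. Scale, centring and direction of that table are thus known from the comparison; the source of the remaining differences is not. It was used as an alternative.

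Each array held 42877 non-control spots of 30367 probes. Spots flagged as non-uniform, from 2 to 64 per array, were set to missing and spots of 1 probe were averaged. The processed signal was divided by the array's 75th percentile, values under 0.005 of it were raised to that floor, and log2 was taken. A probe was kept if it was well above background on at least 4 of the 8 arrays, whatever the group, which kept 24343 probes. No probe was saturated on any array.

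The scanner files give probe names and transcript accessions without gene symbols. Symbols were taken from a RefSeq gene table of the rat assembly GRCr8 by accession, without versions on either side. This named 18643 probes with 1 symbol and left 11724 unnamed here. The build of that table differs from the build of the array header, so no coordinates are given. A gene with several kept probes was represented by the probe with the highest mean, and 21420 genes or unnamed transcripts were tested, 12707 of them with a symbol. Of the 686 called genes with more than 1 kept probe, 67 had a probe that moved the other way.

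The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 8 log2 values of each gene, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method. A gene is called changed at an adjusted p under 0.05. Fold changes are allopurinol over control, and the error given after ± is the moderated standard error with n = 4 in each group unless a standard deviation is named. Where a gene was well above background on no array of the dimmer group, only a lower bound of its fold is given: the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest signal among probes well above background. The measured means of both groups stand beside each bound in the results tables.

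A set of 36 gene lists for kidney cell types, injury, fibrosis, inflammation and metabolism was written before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the 36 lists. Camera with a correlation estimated from the data and limma's fry were the alternatives. Members were also counted with p-values adjusted over the list alone. The rule names, among genes with a symbol whose groups do not overlap, the 8 largest increases and the 8 largest decreases with the dimmer group well above background on at least 2 arrays, and the 4 largest lower bounds. It also names up to 4 members per list with the smallest adjusted p, and these genes fixed beforehand: Xdh, Umps, Havcr1, Lcn2, Spp1, Col1a1, Tgfb1, Acta2, Vim, Umod, Slc34a1, Slc22a12 and Cdkn1a. Members named because they moved against their list, or because few members were called, were chosen after their values were seen. Results of some single genes that the rule names are not reported here.

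Control and allopurinol replicates 1 and 2 lay on slide 1 and replicates 3 and 4 on slide 2, and each slide was 1 scan. Because every slide held 2 arrays of each group, fitting the slide as a block leaves each gene's fold change as it is, apart from genes with a missing value. The alternatives were quantile normalization; normexp background correction with either scaling; the authors' table; another reference for the 75th percentile; no detection filter and a stricter filter; a higher floor of 0.02; the mean of a gene's probes; a trended and robust prior; array weights; the replicate number or the slide as a block; and each array left out in turn. The normexp alternative used the spot and background medians, with an offset of 50, because the columns read here hold no spot mean. A fit with no scaling between arrays was added after the allopurinol arrays were seen to be brighter.

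The fit was tested on simulated data drawn from the means and spreads of 21351 genes, with seeded genes shifted by known amounts. It called 82.1% of the 67 genes shifted by 4 on the log2 scale, 50.7% of the 67 shifted by 2 and 6.06% of the 66 shifted by 1. Of its calls, 7.92% were unchanged genes. In 20 simulated draws the set test found 19 of 20 lists shifted by 1 and called 0 of 673 lists that shared no gene with the shifted one. These simulated genes were independent of each other, which real genes are not. The shifted genes were also a far smaller share of the 21351 than the 23.5% called in the data. The adjusted threshold is stricter where few genes change, so the shares called in the simulation do not give the power in the real data.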

Results

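Gene expression was measured in kidney samples of 10-week-old male rats, 4 samples after the vehicle and 4 after allopurinol at 150 mg/kg, both for 4 weeks. Allopurinol blocks xanthine oxidase, the enzyme that makes urate, and the series title presents the treated animals as a model of renal fibrosis. The comparison of allopurinol with control addresses which transcripts differ in such kidneys. Each sample was run on 1 array, and the number of arrays limits the precision. The 75th percentile of the processed signal was 291 ± 18 on the control arrays and 455 ± 53 on the allopurinol arrays (SD, n = 4 each), a ratio of 1.56 with an exact two-sided permutation p of 0.0286, the smallest that the 70 splits of the arrays allow. Probes well above background made up 75% ± 1.53 of the control arrays and 80.8% ± 0.838 of the allopurinol arrays (SD, n = 4 each, exact permutation p = 0.0286). All fold changes below are relative to each array's own 75th percentile.

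Arrays of 1 group resembled each other more than arrays of different groups. Correlations across genes, which are not independent replicates, ran from 0.897 to 0.937 within control, from 0.919 to 0.961 within allopurinol and from 0.802 to 0.858 between them. The first principal component held 51.85% of the variance and separated the groups. The second held 12.47% and set control replicate 3, at -126, apart from the other control arrays, at 30.4, 33.3 and 73.5.

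**Figure D1:**
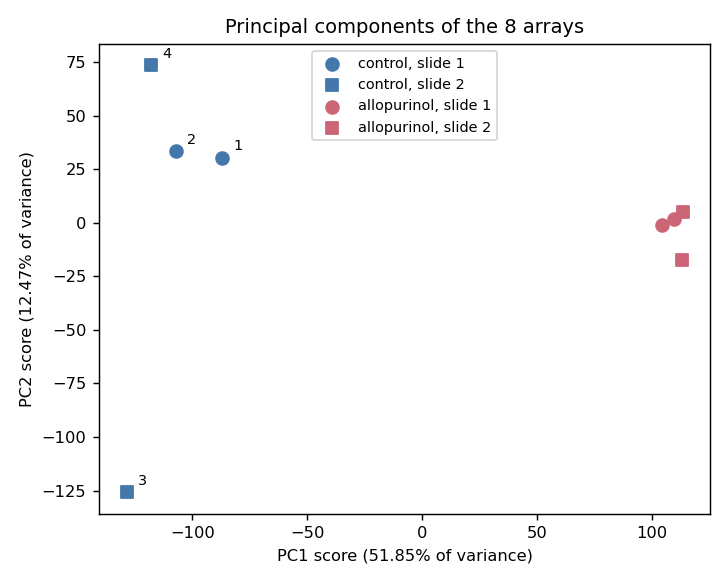
Scores of the 8 arrays on the first principal component (x axis, 51.85% of the variance) and the second (y axis, 12.47%), computed over genes, with colour for the group, marker shape for the slide and the replicate number beside each control array. The 4 allopurinol arrays lie together on the right, and control replicate 3 lies far below the other control arrays on the y axis.

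Kidneys given allopurinol had higher levels of tubular injury, matrix turnover, complement and macrophage transcripts and lower levels of proximal tubule, urate transport and mitochondrial transcripts. Spp1, which encodes the secreted phosphoprotein osteopontin, rose by 10.05 ± 1.01 on the log2 scale, and Slc7a13, an amino acid transporter, fell by 8.58 ± 0.33. Of 21420 genes or unnamed transcripts tested, 5029 (23.5%) were called at an adjusted p under 0.05, 2557 higher and 2472 lower with allopurinol. A change of at least 2-fold was found for 2111 of the higher and 1880 of the lower ones. Among the 12707 with a gene symbol, 1625 were higher and 1585 lower. The 4 allopurinol values lay wholly above or below the 4 control values for 29.9% of genes, where chance gives 2.86%. The log2 fold changes of the 2 slides correlated at 0.739 across all genes, and 4764 genes were called with the slide as a block, which leaves the fold changes as they are because the slides are balanced. Without scaling between arrays, a setting chosen after the allopurinol arrays were seen to be brighter, 5852 genes were called higher and 1135 lower, 83.8% higher against 50.9% with the scaling.

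Of the 36 gene lists, 14 passed the set test upward and 8 downward. With an estimated correlation 12 of these 22 held: matrix turnover, epithelial junctions, tubular injury, macrophage, complement, and immediate early and heat shock upward, and proximal tubule, urate transport, fatty acid oxidation, oxidative phosphorylation, oxidative stress response and renin-angiotensin system downward. The median and the test differed in sign for 2 lists, podocyte and pyrimidine metabolism, neither of which passed, and no passing list changed the sign of its median under any alternative. The medians of 19 of the 22 passing lists moved by over 1.5 times under at least 1 alternative, as did those of all 14 others, and for these the range over the alternatives, or the values that moved, are given below. Of the lists that did not pass, the medians of 8 turned their sign: B and plasma cell, T and NK cell, Wnt signalling, distal tubule, endoplasmic reticulum stress, hypoxia, podocyte and purine metabolism. Of 156 called genes named in the text, 41 lost their call under at least 1 of the 14 other settings that use all 8 arrays, 35 of them with normexp and the 75th percentile. The log2 fold changes of 82 moved by over 1.5 times there, and of 81 with normexp and quantile normalization.

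**Figure D2:**
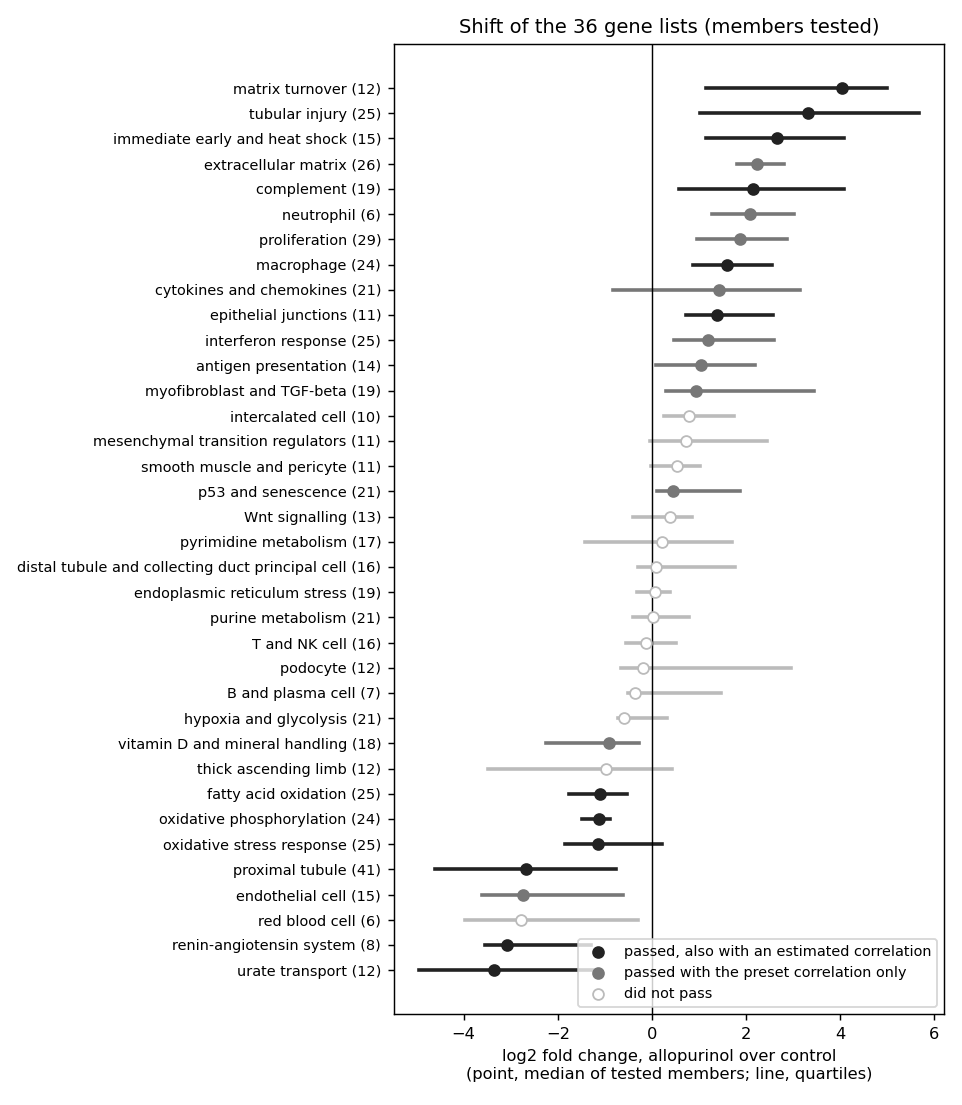
Shift of each of the 36 gene lists (y axis, with the number of members tested) as log2 fold change of allopurinol over control (x axis); points are medians over tested members, lines run between quartiles, and shading marks lists that passed the set test with and without an estimated correlation. Matrix turnover has the highest median at 4.03 and urate transport the lowest at -3.36.

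Tubular injury genes rose. Of 25 tested members, 14 were higher and 2 lower (17 and 2 adjusted over the list alone). The median log2 fold change was 3.32, 1.94 to 3.96 over the alternatives (3.4 on slide 1 and 3.24 on slide 2; adjusted p = 1.03e-07, and adjusted p = 0.0290 with an estimated correlation). Lcn2, an iron-siderophore carrier secreted by injured tubules, rose by 7.58 ± 0.32 (adjusted p = 1.21e-05), and Havcr1, the kidney injury molecule of the proximal tubule, by 5.17 ± 0.38 (adjusted p = 8.84e-05). Spp1 (adjusted p = 0.00039) was well above background on 3 of the 4 control arrays. Cd44, a hyaluronan receptor, rose by 7.49 ± 0.49 (adjusted p = 5.52e-05) against 2 control arrays well above background, and its other probes rose by as little as 2.66. Fgb, which encodes the fibrinogen beta chain, was at least 182-fold higher, with no control array well above background (adjusted p = 2.51e-05). The 2 lower members were Prom1, a membrane glycoprotein of progenitor cells, which fell by 2.64 ± 0.29, and Tff3, a mucosal repair peptide, which fell by 5.22 ± 0.40.

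Outside the lists, the largest increases included Serpina3n, a serine protease inhibitor (8.40 ± 1.04, adjusted p = 0.00101), Itgb4, the laminin-binding integrin subunit of hemidesmosomes (7.33 ± 0.60, adjusted p = 0.000142), Lhfpl2 (7.55 ± 0.86, well above background on 3 control arrays) and Mab21l3 (7.48 ± 0.80, on 2 control arrays). Pdpn, the membrane glycoprotein podoplanin, was at least 286-fold higher, with no control array well above background (adjusted p = 8.86e-06). Among the decreases, Mep1b, a subunit of the brush border protease meprin, fell by 9.78 ± 1.05, Hnmt, which methylates histamine, fell by 9.15 ± 0.64, Haao, an enzyme of tryptophan breakdown, fell by 9.08 ± 1.02, and Slc22a22, an organic anion carrier, fell by 8.11 ± 1.26. These genes were well above background on 2 of the 4 allopurinol arrays, so their values lean on the floor, and that of Mep1b (adjusted p = 0.000523) was -8.79 with the floor at 0.02 and -5.95 with normexp and quantile normalization. Slc7a13 (adjusted p = 1.05e-05), Gucy1b2, a guanylate cyclase subunit, which fell by 8.04 ± 0.28, and Cacng5, a calcium channel subunit, which fell by 8.00 ± 0.27, were well above background on every array. Cyp2c11, a male-specific steroid hydroxylase, was at least 273-fold lower and Iqch at least 229-fold lower, with no allopurinol array well above background.

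Proximal tubule genes fell. Of 41 tested members, 29 were lower and 4 higher (30 and 5 adjusted over the list alone). The median log2 fold change was -2.68 (-3.07 on slide 1 and -2.42 on slide 2; adjusted p = 2.51e-11, and adjusted p = 0.0153 with an estimated correlation). Slco1a1, an organic anion transporter, fell by 9.34 ± 0.97 (well above background on 2 allopurinol arrays), Pck1, the key enzyme of gluconeogenesis, fell by 6.54 ± 0.37, Miox, which breaks down inositol, fell by 5.64 ± 0.29, and Slc34a1, the sodium-phosphate cotransporter, fell by 4.53 ± 0.39 (adjusted p = 0.000186). The 4 higher members were Slc7a7, an amino acid transporter (4.95 ± 0.79), Slc5a12, a lactate transporter (4.61 ± 0.93, with its call lost with normexp and the 75th percentile, adjusted p = 0.0715), and the glucose transporters Slc5a2 (3.04 ± 0.66) and Slc2a2 (2.01 ± 0.35). Slc5a12 was well above background on 1 control array, and its value was 3.41 with the floor at 0.02 and 1.37 and 1.04 under the 2 normexp scalings. That of Slc7a7 was 2.22 and 1.86 under the normexp scalings. Urate transport genes fell too, with 8 of 12 lower and 2 higher, Slc5a12 and the efflux pump Abcc4 (1.97 ± 0.30), the same counts adjusted over the list alone. Their median was -3.36 (-3.30 and -3.28 on the slides; adjusted p = 0.000889, and adjusted p = 0.0316 with an estimated correlation). Slc22a12, the urate reabsorption transporter, fell by 5.35 ± 0.43 (adjusted p = 0.000126), Slc22a6, an organic anion transporter, fell by 6.51 ± 0.37, Slc17a3 fell by 3.87 ± 0.30, and Abcg2, a urate exporter, fell by 2.86 ± 0.30. Most urate transport genes, among them Slc22a12, Slc22a6, Slc17a3 and Slc5a12, also stand on the proximal tubule list, so the results of these lists are not independent.

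Genes of mitochondrial energy production fell. Of 24 oxidative phosphorylation genes, 22 were lower and 0 higher (23 and 0 adjusted over the list alone). The median was -1.12, or -0.48 without scaling (-1.22 and -1.09 on the slides; adjusted p = 9.81e-12, and adjusted p = 0.0290 with an estimated correlation). Cycs, cytochrome c, fell by 2.75 ± 0.18, Uqcrfs1 fell by 1.71 ± 0.19 and Sdha fell by 1.70 ± 0.17. Of 25 fatty acid oxidation genes, 15 were lower and 1 higher, also adjusted over the list alone. The median was -1.11, or -0.47 without scaling (-1.13 and -1.14; adjusted p = 1.60e-06, and adjusted p = 0.0316 with an estimated correlation). Ehhadh, a peroxisomal enzyme, fell by 4.83 ± 0.35 and Acadm fell by 2.54 ± 0.22, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, was the higher one (5.24 ± 0.46). Oxidative stress response genes fell, with 12 of 25 lower and 0 higher (14 and 1 adjusted over the list alone) and a median of -1.14, or -0.50 without scaling (-1.50 and -0.78; adjusted p = 0.000207, and adjusted p = 0.0290 with an estimated correlation). Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, changed by -6.60 ± 0.30 and -2.91 ± 0.25, Cat, catalase, by -4.29 ± 0.30, and Sod1 by -2.15 ± 0.17. Of 8 genes of the renin-angiotensin system, 6 were lower and 0 higher, also adjusted over the list alone. The median was -3.09 (-2.91 and -3.15; adjusted p = 4.76e-06, and adjusted p = 0.0290 with an estimated correlation). The median was -1.44 without a detection filter, -1.42 with normexp and the 75th percentile and -1.45 with normexp and quantile normalization. Agt, angiotensinogen, fell by 3.51 ± 0.40, and the peptidases Mme and Enpep changed by -3.35 ± 0.25 and -2.83 ± 0.22.

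Extracellular matrix genes rose. Of 26 tested members, 16 were higher and 0 lower (18 and 0 adjusted over the list alone). The median was 2.23, 1.40 to 2.87 over the alternatives (2.24 and 2.31 on the slides; adjusted p = 4.40e-09). The list's call was lost at an adjusted p = 0.0841 with an estimated correlation. Col1a1, a chain of type I collagen, rose by 2.12 ± 0.38 (adjusted p = 0.00615), Col4a1, a basement membrane collagen, by 2.81 ± 0.29, Fbln1 by 4.43 ± 0.53 and Pcolce, a collagen-processing enhancer, by 3.34 ± 0.28. Of 12 matrix turnover genes, 8 were higher and 2 lower, also adjusted over the list alone. The median was 4.03, or 3.87 with bounds in place of unmeasured folds and 2.39 to 4.67 over the alternatives (3.84 and 4.43 on the slides; adjusted p = 8.14e-05, and adjusted p = 0.0290 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose by 5.99 ± 0.34, Adamts1 by 4.77 ± 0.42 and Plat, a plasminogen activator, by 4.30 ± 0.43. Mmp12, macrophage elastase, was at least 15.7-fold higher. The lower members were Timp3, which fell by 1.95 ± 0.31, and Plau, which fell by 1.36 ± 0.37 and lost its call without control replicate 2, 3 or 4 or allopurinol replicate 2, 3 or 4 (adjusted p up to 0.0878) and under 4 other settings (up to 0.173, without scaling).

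Myofibroblast and TGF-beta genes were higher as a list. Of 19 members, 6 were higher and 2 lower, also adjusted over the list alone. The median was 0.94, 0.42 to 1.58 over the alternatives and 1.44 without allopurinol replicate 3 (1.31 and 0.83 on the slides; adjusted p = 0.00411, and adjusted p = 0.171 with an estimated correlation). Vim, an intermediate filament of mesenchymal cells, rose by 6.14 ± 0.73 (adjusted p = 0.000832), Ltbp2, a latent TGF-beta binding protein, by 6.68 ± 0.87, and Tgfb2 by 3.20 ± 0.27 on the probe used and 8.22 on another. The log2 fold change of Tgfb1 was 1.67 ± 1.03 (adjusted p = 0.278) and that of Acta2, smooth muscle actin, 1.17 ± 0.51 (adjusted p = 0.137, and adjusted p = 0.0374 without scaling between arrays), neither past the threshold. The 2 lower members were Tgfbi, which fell by 2.18 ± 0.35, and Pdgfra, which fell by 1.25 ± 0.31 and lost its call without control replicate 2 or 3 or allopurinol replicate 1 or 2 (adjusted p up to 0.0621) and under 3 other settings (up to 0.205, without scaling). The mesenchymal transition regulators did not pass, with a median of 0.73, 0.11 to 1.37 over the alternatives and 0.20 to 1.11 with 1 array left out (0.90 and 0.57; adjusted p = 0.0632, and adjusted p = 0.195 with an estimated correlation). Of 11 members 3 were higher, Vim, S100a4 (5.09 ± 1.11) and Twist2 (2.66 ± 0.55), and 0 lower (4 and 0 adjusted over the list alone). Epithelial junction genes rose, with 6 of 11 higher and 0 lower (7 and 0 adjusted over the list alone) and a median of 1.38 (1.66 and 1.1; adjusted p = 0.000434, and adjusted p = 0.0296 with an estimated correlation). Cldn4, a tight junction protein, rose by 7.48 ± 1.13 (well above background on 3 control arrays), Cldn7 by 4.44 ± 0.39, Cldn1 by 2.55 ± 0.21 and Cdh16, the kidney cadherin, by 1.14 ± 0.22. With normexp and the 75th percentile the calls of Twist2 (adjusted p = 0.166) and Cdh16 (0.107) were lost, that of Twist2 also with normexp and quantile normalization (0.0555).

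**Figure D3:**
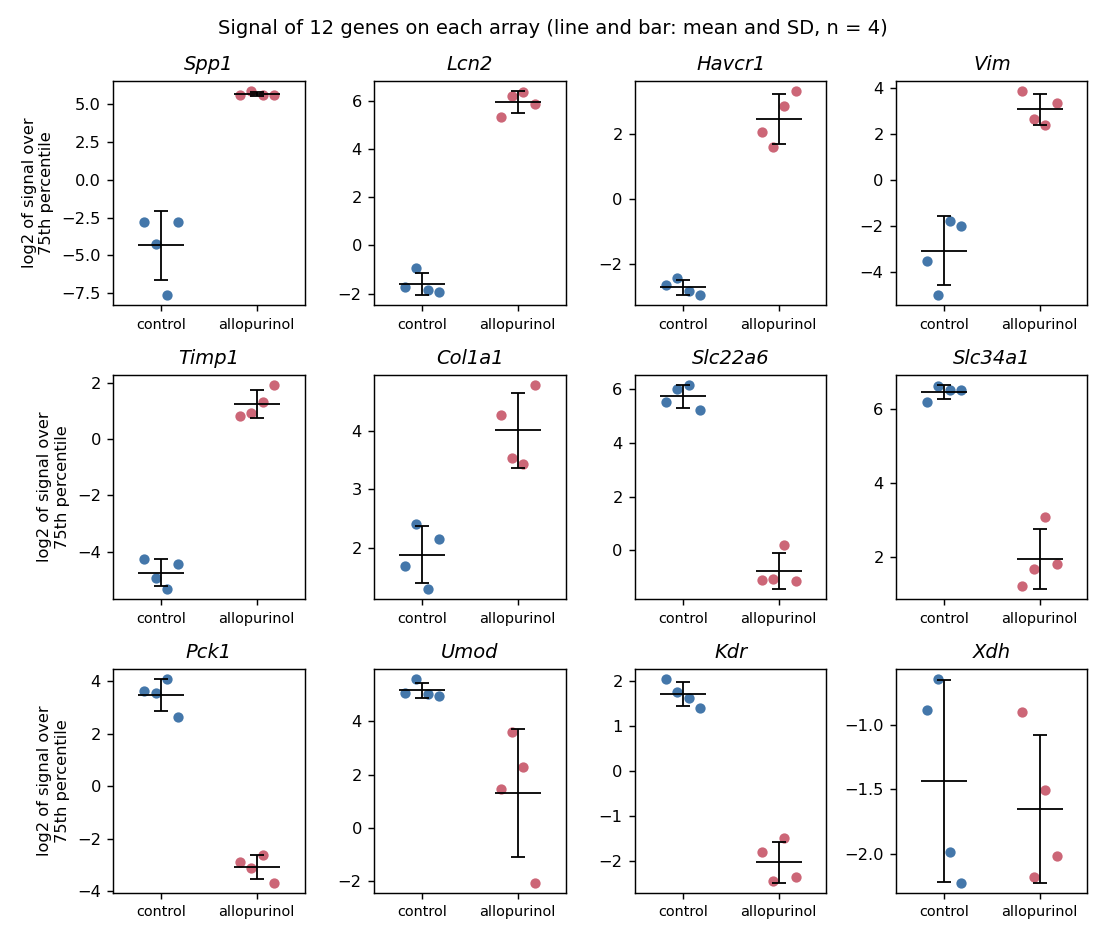
Signal of 12 genes on each array as log2 of the processed signal over the array's 75th percentile (y axis), by group (x axis); points are arrays, and line and bars give the mean and SD (n = 4). Groups are apart for every gene shown other than Xdh, whose log2 fold change was -0.21.

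Macrophage and complement genes rose. Of 24 macrophage genes, 11 were higher and 0 lower (14 and 0 adjusted over the list alone). The median was 1.58, 0.95 to 2.23 over the alternatives (1.27 and 2.03 on the slides; adjusted p = 4.76e-06, and adjusted p = 0.0322 with an estimated correlation). Lgals3, galectin-3, rose by 5.68 ± 0.30, Gpnmb by 4.46 ± 0.31, Trem2, a lipid-sensing receptor, by 3.66 ± 0.49 and Lyz2, lysozyme, by 1.69 ± 0.23. Lgals3 and Gpnmb also stand on the tubular injury list, and the 13 members not called include Adgre1 (-0.34 ± 0.55), Csf1r, the receptor of a macrophage growth factor (-0.24 ± 0.47), and Cd86 (-0.97 ± 0.43). Of 19 complement genes, 10 were higher and 0 lower (10 and 1 adjusted over the list alone). The median was 2.14, 1.30 to 2.78 over the alternatives (1.69 and 2.45; adjusted p = 2.28e-05, and adjusted p = 0.0290 with an estimated correlation). Cfi rose by 6.05 ± 0.87, Cfd by 5.13 ± 0.39, C2 by 4.88 ± 0.66 and C4a by 3.67 ± 0.24. Cfi was well above background on 2 control arrays, and its value was 2.38 and 2.01 under the 2 normexp scalings. That of Cfd was 2.38 and 2.16 there. Cytokine and chemokine genes rose, with 10 of 21 higher and 3 lower (11 and 3 adjusted over the list alone) and a median of 1.42, 0.41 to 2.05 over the alternatives (0.96 and 1.91; adjusted p = 0.0120, and adjusted p = 0.140 with an estimated correlation). Ccl2, which attracts monocytes, rose by 4.97 ± 0.56, and Ccl20 was at least 53-fold higher. Under the 2 normexp scalings the value of Ccl2 was 2.07 and 1.79. Cxcl12 fell by 4.03 ± 0.36, Cxcl11 fell by 1.56 ± 0.44 and Ccl19 fell by 1.23 ± 0.30. The call of Cxcl11 was lost without any 1 array other than control replicate 4 (adjusted p up to 0.0921) and under 3 other settings (up to 0.128). That of Ccl19 was lost without control replicate 1 or 4 or allopurinol replicate 4 (adjusted p up to 0.0631) and under 3 other settings (up to 0.234).

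Antigen presentation and interferon genes rose. Of 14 antigen presentation genes, 6 were higher and 0 lower (7 and 1 adjusted over the list alone). The median was 1.03, 0.60 to 1.67 over the alternatives (0.62 and 1.18 on the slides; adjusted p = 0.00536, and adjusted p = 0.137 with an estimated correlation). The immunoproteasome subunits Psmb9 and Psmb8 rose by 4.64 ± 0.48 and by 3.23 ± 0.43. Of 25 interferon response genes, 9 were higher and 2 lower, also adjusted over the list alone. The median was 1.18, 0.51 to 1.82 over the alternatives (1.05 and 1.62; adjusted p = 0.00283, and adjusted p = 0.0841 with an estimated correlation). The transcription factors Irf7 and Irf1 rose by 3.52 ± 0.50 and by 3.29 ± 0.43. The antiviral genes Oas2 and Mx2 changed by -1.13 ± 0.20 and -0.78 ± 0.19, and both calls were lost elsewhere. That of Oas2 was lost with normexp and the 75th percentile (-0.26, adjusted p = 0.713) and without scaling (adjusted p = 0.0685). That of Mx2 was lost with quantile normalization (-0.29, adjusted p = 0.302), normexp and quantile normalization (0.209), the replicate block (0.0727) and no scaling (0.560), and without control replicate 2 or allopurinol replicate 3 or 4 (up to 0.0549). The neutrophil list rose with 2 of 6 members higher and 0 lower, also adjusted over the list alone, and a median of 2.08, 0.28 to 2.72 over the alternatives (1.66 and 1.97; adjusted p = 0.00642, and adjusted p = 0.0615 with an estimated correlation). These were the calprotectin subunits, S100a8 at least 33.9-fold higher and S100a9 by 2.77 ± 0.34, well above background on 1 control array and not called with normexp and the 75th percentile (0.93, adjusted p = 0.330). T and NK cell genes did not pass (median -0.14, -0.34 to 0.46 over the alternatives; -0.18 and -0.11 on the slides; adjusted p = 0.718), and 1 of 16 was called, the costimulatory receptor Cd28 (-2.88 ± 0.46). Nor did B and plasma cell genes (median -0.35, -0.55 to 0.51 over the alternatives; -0.10 and -0.60 on the slides; adjusted p = 0.866), with 1 of 7 called, Pou2af1, a B cell coactivator (3.28 ± 0.65). Both single calls held adjusted over the list alone, but that of Cd28 was lost with normexp and the 75th percentile (-0.22, adjusted p = 0.830).

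Endothelial genes fell. Of 15 tested members, 8 were lower and 0 higher (9 and 0 adjusted over the list alone). The median was -2.74 (-2.35 and -2.47 on the slides; adjusted p = 0.000440, and adjusted p = 0.0615 with an estimated correlation). Plvap, the diaphragm protein of fenestrated vessels, fell by 4.40 ± 0.36, Kdr, the main VEGF receptor, fell by 3.73 ± 0.28, Vwf, von Willebrand factor, fell by 3.50 ± 0.50, and Tek, the angiopoietin receptor, fell by 4.09 ± 0.61 with 1 allopurinol array well above background. The list's median was -0.42 with normexp and the 75th percentile, where the call of Tek was lost (adjusted p = 0.959), and -0.90 with normexp and quantile normalization. The red blood cell list did not pass (median -2.78, -3.87 to -0.99 over the alternatives; -2.73 and -2.77 on the slides; adjusted p = 0.0861), with 3 of 6 lower and 0 higher (3 and 1 adjusted over the list alone). The lower members were the hemoglobin genes Hbb-b1, Hbb and Hba-a1, which changed by -4.07 ± 0.66, -4.01 ± 0.71 and -3.87 ± 0.57, and the members not called include Ahsp (3.35 ± 1.24) and Slc4a1 (0.15 ± 1.13). Smooth muscle and pericyte genes did not pass (median 0.54, 0.10 to 1.17 over the alternatives; 0.56 and 0.31; adjusted p = 0.446), with 1 of 11 higher and 0 adjusted over the list alone. This was Cspg4 (2.35 ± 0.71), which lost its call without any 1 array other than control replicate 3 (adjusted p up to 0.105) and under 5 other settings, among them the slide as a block (adjusted p = 0.0631) and normexp with the 75th percentile (0.116).

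Genes of the thick ascending limb did not pass as a list (median -0.97, -1.18 to -0.33 over the alternatives; -0.71 and -1.62 on the slides; adjusted p = 0.125), with 5 of 12 lower and 2 higher, also adjusted over the list alone. Egf, epidermal growth factor, fell by 6.29 ± 0.69, Umod, uromodulin, fell by 3.85 ± 1.06 (adjusted p = 0.0345), Cldn10 fell by 3.57 ± 0.56, Casr, the calcium-sensing receptor, fell by 3.45 ± 0.87 and Cldn16 fell by 1.17 ± 0.35, while Ptger3, a prostaglandin receptor, rose by 0.96 ± 0.27. Calls were lost for Umod without any control replicate or allopurinol replicate 1 or 3 (adjusted p up to 0.0777) and for Casr without control replicate 1 or 2 or allopurinol replicate 3 or 4 (up to 0.0691). They were also lost for Cldn16 without any 1 array other than allopurinol replicate 2 (up to 0.110) and for Ptger3 without any 1 array other than control replicate 3 (up to 0.0938). Under other settings calls were lost for Cldn16 in 8 (adjusted p = 0.0640 with the slide as a block, up to 0.372), Ptger3 in 6 (0.0546 with the slide as a block, up to 0.217), Umod in 2 (up to 0.0571) and Casr with normexp and the 75th percentile (0.447). Distal tubule and principal cell genes did not pass (median 0.09, -0.05 to 0.78 over the alternatives; 0.50 and 0.09; adjusted p = 0.410), with 3 of 16 higher and 1 lower, also adjusted over the list alone. The water channels Aqp4 (4.15 ± 0.87) and Aqp2 (1.93 ± 0.48) and the calcium channel Trpv5 (2.06 ± 0.53) were higher, and S100g, calbindin-D9k, fell by 5.79 ± 0.81. The call of Aqp4 was lost with the mean of its 3 probes (2.17, adjusted p = 0.0641), which ranged from 0.52 to 4.15, with probes well above background on all 8 arrays (0.52, adjusted p = 0.380) and with normexp under either scaling (adjusted p = 0.171 and 0.0883). The call of Aqp2 was lost without control replicate 3 or 4 or allopurinol replicate 1 or 3 (adjusted p up to 0.0630) and under 2 other settings (up to 0.0903). That of Trpv5 was lost without control replicate 1, 2 or 3 or allopurinol replicate 1 (up to 0.0673) and under 4 other settings (up to 0.316). That of S100g was lost with normexp and the 75th percentile (adjusted p = 0.0703). Intercalated cell genes did not pass (median 0.79, 0.16 without allopurinol replicate 1 to 1.43 without scaling; 0.42 and 1.13; adjusted p = 0.273), and 0 of 10 were called, also adjusted over the list alone.

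Podocyte genes did not pass (median -0.19, -0.45 to 0.52 over the alternatives; 0.03 and 0.18 on the slides; adjusted p = 0.667), with 4 of 12 higher and 2 lower (5 and 2 adjusted over the list alone). Plce1 (3.84 ± 1.04), Nes, the intermediate filament nestin (2.98 ± 0.30), Ptpro (2.94 ± 0.52) and Synpo, synaptopodin (1.78 ± 0.52), were higher, and Podxl, podocalyxin, and Magi2 changed by -1.99 ± 0.33 and -1.12 ± 0.31. Plce1 was well above background on 1 control array, and its value was 1.32 and 0.66 under the 2 normexp scalings. Calls were lost for Plce1 without control replicate 2, 3 or 4 or allopurinol replicate 2, 3 or 4 (adjusted p up to 0.0863). They were also lost for Synpo without any control replicate or allopurinol replicate 2 or 4 (up to 0.0981) or with the slide as a block (0.0593) and for Magi2 without control replicate 1, 2 or 3 or allopurinol replicate 3 or 4 (up to 0.0885). Under other settings with all arrays, calls were lost for Plce1 in 4 (adjusted p up to 0.103), Synpo in 5 (up to 0.116) and Magi2 in 5 (up to 0.684, where it turned to 0.41).

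Xdh, the enzyme that allopurinol inhibits, was not called, with a log2 fold change of -0.21 ± 0.45 (adjusted p = 0.757), -0.77 on slide 1 and 0.35 on slide 2. Purine metabolism genes did not pass (median 0.03, -0.09 to 0.66 over the alternatives; -0.05 and 0.35; adjusted p = 0.670), with 4 of 21 higher and 1 lower, also adjusted over the list alone. Impdh1 (3.87 ± 1.16) and Impdh2 (1.92 ± 0.45), which make guanine nucleotides, Ampd3, an AMP deaminase (2.20 ± 0.50), and Prps2 (1.93 ± 0.58) were higher, and Prps1 fell by 0.71 ± 0.21. Calls were lost for Impdh1 without any 1 array other than control replicate 2 (adjusted p up to 0.107), for Prps2 without any other than control replicate 1 (up to 0.106), for Prps1 without any 1 of the 8 arrays (up to 0.0988) and for Impdh2 without allopurinol replicate 4 (0.0534). Under other settings calls were lost for Prps1 in 8 (adjusted p = 0.0564 with the slide as a block, up to 0.798), Prps2 in 4 (up to 0.0739), Impdh1 in 3 (0.0545 with the slide as a block, up to 0.0745), Impdh2 in 2 (up to 0.0538) and Ampd3 in 2 (up to 0.110). Umps, which completes pyrimidine synthesis, had a log2 fold change of -1.28 ± 0.55 (adjusted p = 0.130, and adjusted p = 0.0391 with normexp and quantile normalization). Pyrimidine metabolism genes did not pass (median 0.21, 0.06 to 0.84 over the alternatives, mean -0.50; 0.34 and 0.09 on the slides; adjusted p = 0.718), with 4 of 17 lower and 2 higher (4 and 3 adjusted over the list alone). The breakdown enzymes Dpys, Upb1 and Upp2 changed by -7.10 ± 0.42, -6.26 ± 0.54 and -4.40 ± 0.53, and the kinase Cmpk1 by -1.42 ± 0.19. The higher members were Dctd, at least 5.86-fold with no control array well above background, and Ctps1 (1.77 ± 0.43). With normexp and the 75th percentile the calls of Upp2 (-0.75, adjusted p = 0.568), Dctd (adjusted p = 0.294) and Ctps1 (0.0972) were lost, that of Ctps1 also with the mean of its probes (0.0690) and without control replicate 1 or 2 or allopurinol replicate 4 (up to 0.0591).

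Vitamin D and mineral handling genes fell, with 5 of 18 lower and 2 higher (7 and 2 adjusted over the list alone) and a median of -0.92, -1.22 to -0.29 over the alternatives (-1.61 and -0.61 on the slides; adjusted p = 0.0162, and adjusted p = 0.0841 with an estimated correlation). The lower members were S100g, Slc34a1, Casr, Kl, the FGF23 co-receptor klotho, which fell by 2.77 ± 0.39, and Pth1r, the parathyroid hormone receptor, which fell by 2.43 ± 0.34. The calcium channels were the higher members, Trpv5 and Trpv6, the latter at least 29.2-fold.

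Proliferation and immediate early genes rose as lists. Of 29 proliferation genes, 11 were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 1.87, 0.59 to 2.51 over the alternatives (1.29 and 2.42 on the slides; adjusted p = 3.52e-05, and adjusted p = 0.165 with an estimated correlation). The mitotic kinase Plk1 rose by 4.64 ± 0.82 and the cyclin Ccnb1 by 3.88 ± 0.74. Under the 2 normexp scalings the value of Plk1 was 2.32 and 1.99. Of 15 immediate early and heat shock genes, 11 were higher and 0 lower (12 and 1 adjusted over the list alone). The median was 2.66, 1.71 to 3.30 over the alternatives (2.38 and 2.87; adjusted p = 1.09e-05, and adjusted p = 0.0290 with an estimated correlation). Fos rose by 5.48 ± 0.67, with 1 control array well above background, Klf6 by 4.13 ± 0.57, and Egr1 was at least 15.5-fold higher, a call lost with normexp and the 75th percentile (adjusted p = 0.0987). The p53 and senescence list passed the set test, but 18 of its 21 members were not called, 3 were higher and 0 lower, also adjusted over the list alone. Its median was 0.44, or 1.07 without scaling (0.33 and 0.53; adjusted p = 0.0131, and adjusted p = 0.0912 with an estimated correlation). The higher members were Bbc3, a death-promoting Bcl-2 relative (5.13 ± 1.08), Btg2 (4.01 ± 0.43) and Gadd45b (2.78 ± 0.66), whose call was lost without control replicate 1 or allopurinol replicate 2 or 3 (adjusted p up to 0.0530). Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 0.44 ± 0.26 (adjusted p = 0.264) on the probe used and of 6.26 on another. It was called with the mean of its probes (adjusted p = 0.00618) and without scaling between arrays (adjusted p = 0.0169).

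Endoplasmic reticulum stress genes did not pass (median 0.06, -0.03 to 0.70 over the alternatives; 0.17 and -0.02 on the slides; adjusted p = 0.741), with 2 of 19 higher and 2 lower, also adjusted over the list alone. Atf3, a stress-induced transcription factor, rose by 5.50 ± 0.91 and Asns, asparagine synthetase, by 5.49 ± 0.48, while Dnajc3 and Herpud1 changed by -1.27 ± 0.19 and -1.35 ± 0.33. Under the 2 normexp scalings the value of Atf3 was 2.40 and 2.17. Hypoxia and glycolysis genes did not pass (median -0.60, -0.63 to 0.04 over the alternatives; -0.37 and -0.65 on the slides; adjusted p = 0.190), with 6 of 21 lower and 1 higher (7 and 1 adjusted over the list alone), the glycolytic enzyme Pfkp (2.98 ± 0.36). Wnt signalling genes did not pass (median 0.38, -0.15 to 1.02 over the alternatives; 0.61 and -0.08; adjusted p = 0.653), with 2 of 13 higher and 1 lower, also adjusted over the list alone. Wnt10a was at least 13.3-fold higher, Dkk3 rose by 3.05 ± 0.83 and Wnt5a fell by 1.97 ± 0.29. Calls were lost for Herpud1 without control replicate 3 or 4 (adjusted p up to 0.0523) and for Dkk3 without control replicate 1 or any allopurinol replicate (up to 0.0800). With normexp and the 75th percentile the calls of Wnt10a (adjusted p = 0.0615), Wnt5a (-1.07, adjusted p = 0.0741) and Herpud1 (0.0589) were lost, without scaling those of Herpud1 (0.127) and Dnajc3 (0.0602), and that of Dkk3 under 2 other settings (up to 0.0577).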

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

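All tests of explanations here were chosen after the results were seen; the counts of splits were laid down by a fixed rule, but their expected outcomes were also written after the result was seen. Single values set apart from the other 3 of their group, relative to the group's range, were looked for in 336 groups of 4. These covered 166 genes named in the text and the array measures, and 25 were found. Chance gives about 1 in 20 groups where values are continuous, a rate that does not hold for groups with values tied at the floor. Where the other 3 all lay at the floor, as for Mmp12, S100a8 and Plce1 in control, any difference is flagged, however small. Values are log2 of the signal over the array's 75th percentile.

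The count of called genes is the widest pattern. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many calls, 5029 against at most 6 in any other split, and likewise 1 of 35 for calls of at least 2-fold, 3991 against at most 6. A share of 1 in 35 is the smallest that these splits allow. The other splits mix the groups, which widens the spread within each side where the groups differ, so their low counts do not measure chance alone. Chance is thus unlikely for both counts but not excluded. Of the genes flagged well above background on all 8 arrays, 25.1% were called, which argues against signals without that flag as the whole source. The flag still passes dim signals, such as Gucy1b2 with allopurinol values of -5.99 to -5.63. Dim signals as a source therefore stay open. That choice of genes leaves the unequal brightness and its scaling in place, so it does not bear on them. With normexp and the 75th percentile 2013 genes were called, and without scaling 83.8% of the calls were higher. For the count of passing lists chance cannot be excluded: 2 of the 35 splits gave as many, 22 for the real one and 23 for another, although the 18 splits with 2 arrays of each group on either side gave at most 3 and the split by slide gave 0 genes and 0 lists. The split with 23 lists set control replicates 1, 2 and 3 and allopurinol replicate 1 against the rest, so it still carries part of the group difference. The calls and the splits compare treated with control arrays, so they bear on a difference between the groups, which an effect of allopurinol would give. They do not tell such an effect apart from other differences between the groups, array brightness among them.

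Proximal tubule genes were lower. A smaller share of proximal tubule cells alone would raise the markers of every other cell type alike, but the endothelial list had a median of -2.74 and an upper quartile of -0.62, which lay 1.47 below the lower quartile of the macrophage list without its 2 injury genes. The endothelial median was -0.42 with normexp and the 75th percentile, where the upper quartile was 0.26, and -0.90 with normexp and quantile normalization, and the gap to the macrophage list was at least 0.38 under every scaling tried. The scaling of the arrays is argued against as the whole cause, since without scaling, which leaves the allopurinol arrays brighter, the list's median was -2.04 and its upper quartile -0.14. Lower expression within the cells, a smaller share of them joined to other changes, and the treatment itself may each contribute and were not tested apart.

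Endothelial genes were lower. Less interstitial tissue alone, with unchanged levels in its cells, is argued against by the macrophage list, whose lower quartile was 0.85 without its 2 injury genes, and by the extracellular matrix list, whose lower quartile was 1.80. These lists can also rise through higher levels per cell, so they do not measure the amount of interstitial tissue, which stays open. Fewer blood-filled vessels in those samples, whether from the animals or from how the kidneys were bled, would lower the red blood cell list, which had a median of -2.78 and did not pass (adjusted p = 0.0861). Its 3 hemoglobin genes were lower while Ahsp (3.35) and Slc4a1 (0.15) were not. Slc4a1 also stands on the intercalated cell list, and the value of Ahsp was 1.27 and 1.14 under the 2 normexp scalings, so both are weak measures of blood. The set test passed downward under some alternatives, among them normexp with the 75th percentile (adjusted p = 0.00251) and the stricter filter (0.0249). It did not pass with quantile normalization (0.126), so the test leaves this open. A loss of vessels with the treatment stays open too and was not tested.

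Among injury, matrix and immune genes, Itgb4 was -2.59 in control replicate 1 against -4.96 to -4.57 in the other controls, Pcolce 2.00 there against 1.09 to 1.17, Cdh16 1.99 against 2.50 to 2.57 and Lyz2 1.41 against 1.01 to 1.08. In control replicate 4, Mmp12 was -7.63 with the others at the floor of -7.64, S100a8 was -6.63 against -7.64 and S100a4 was -6.48 against -2.09 to -1.47. Psmb9 was -3.86 in control replicate 2 against -2.10 to -1.84, and Ccl19 was -0.34 there against -0.17. Hba-a1 was 4.05 in control replicate 3 against 3.31 to 3.38. With allopurinol, Ccl2 was -0.76 in replicate 3 against -0.33 to -0.28, C2 was 1.71 in replicate 1 against 0.19 to 0.42, and Klf6 was -0.10 in replicate 4 against 1.81 to 2.03.

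Among tubular, metabolic and other genes, Abcg2 was 2.02 in control replicate 2 against 2.47 to 2.56 and Acadm 2.95 there against 3.54 to 3.64. Uqcrfs1 was 4.65 in control replicate 4 against 4.22 to 4.29. Slc5a12 was -3.37 in control replicate 3 against -7.64 to -6.98, and Kl was 0.60 there against 1.98 to 2.19. Plce1 was -5.43 in control replicate 1 against -7.64, and -6.38 in allopurinol replicate 1 against -2.51 to -2.01. With allopurinol, Gucy1b2 was -5.99 in replicate 1 against -5.67 to -5.63, Slc22a6 was 0.21 in replicate 3 against -1.16 to -1.07, Ehhadh was -3.68 in replicate 3 against -2.89 to -2.78, Slc7a7 was 0.52 in replicate 4 against -0.75 to -0.62, and Tek was -5.15 in replicate 4 against -7.64 to -7.49.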

How the results depend on the processing

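The fit without scaling between arrays was chosen after the data were seen; the other alternatives were fixed before. Over the named genes and all alternatives, 4061 values kept direction and side of the threshold, 250 lost and 29 gained a call, and 1 turned its direction, Magi2 with normexp and the 75th percentile (0.41, adjusted p = 0.684). Over the lists, 831 outcomes were kept, 16 lost and 16 gained. The cause of the changes below was not tested unless stated. The median of all genes moved from -0.03 to -0.11 with quantile normalization, to 0.36 with normexp and the 75th percentile and to 0.61 without scaling. Counts of calls within 1.5 times of the main ones were found under the alternatives not given here. With normexp and the 75th percentile 2013 genes were called, 1040 higher and 973 lower, 1040 and 971 of them by at least 2-fold; 1948 of the 5029 were kept and 415 had the other sign. Normexp with quantile normalization gave 1341 and 1177 calls of at least 2-fold. Both add an offset of 50 before scaling. With quantile normalization after it the median of all genes stayed near 0, at -0.04. With the 75th percentile it was 0.36, so folds there were not simply pulled toward 0. The podocyte median, for example, went from -0.19 to -0.08 with normexp and quantile normalization and to 0.52 with normexp and the 75th percentile. Without scaling 5852 were higher and 1135 lower, 4985 and 994 by at least 2-fold. Leaving out each array, with fewer samples, gave 1609 to 2205 higher calls, with 1609 without allopurinol replicate 4 and 1625 without allopurinol replicate 2, and 3386 to 4190 calls in all. The replicate numbers do not pair the samples, since the deviations of equally numbered arrays correlated at 0.011, 0.010, 0.048 and -0.016; with the number as a block 3260 genes were called, 1644 higher and 1616 lower.

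With an estimated correlation 6 lists passed upward, and calls were lost for antigen presentation (adjusted p = 0.137), cytokines (0.140), endothelial cell (0.0615), extracellular matrix (0.0841), interferon (0.0841), myofibroblast (0.171), neutrophil (0.0615), p53 (0.0912), proliferation (0.165) and vitamin D (0.0841). Normexp with the 75th percentile lost neutrophil (0.0528) and p53 (0.0904) and gained mesenchymal transition (0.0436), red blood cell (0.00251) and thick ascending limb (0.00987); normexp with quantile normalization lost neutrophil (0.0511). Genes well above background on all 8 arrays lost cytokines (0.359) and myofibroblast (0.0764) and gained red blood cell (0.0249), with too few neutrophil members left to test. The mean of probes gained mesenchymal transition (0.0491) and the replicate block red blood cell (0.0437). Without scaling cytokines was lost (0.186), and red blood cell (0.00469) and thick ascending limb (0.00760) gained. Fry, which asks only whether a list moves one way, gained hypoxia (0.00525), mesenchymal transition (0.00692), pyrimidine (0.00550), red blood cell (0.0134) and thick ascending limb (0.0297). Leaving out each array gave 0.0171 to 0.132 for mesenchymal transition, which passed without control replicate 4 and without allopurinol replicate 2 (0.0480), and 0.0442 to 0.141 for red blood cell, which passed without control replicate 4. Signal over background limits 262 called genes to a bound of their fold.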

Other observations

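All tests in this part were chosen after the results were seen. Some gene families, grouped by their symbols and in part with members on the fixed lists, also moved together, and others did not. Of 35 groups screened, 34 named by symbol and 1 of motile cilia genes, 20 passed camera after adjustment over the 35, and 8 of these also with an estimated correlation. Those not described below passed with the preset correlation only: Tub (adjusted p = 0.00350) and Itg (0.00907) upward, and Mrpl and Mrps (0.00335), Acsm (0.0117) and Vom (0.0185) downward. The median of Vom, vomeronasal receptors, was -0.34. It turned to 0.48 with normexp and the 75th percentile and to 0.30 without scaling. A pass with the preset correlation alone can thus rest on a small shift that depends on the scaling.

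Some transport and detoxification families fell, and others passed only with the preset correlation. Of 16 Slc22a organic ion transporters, 12 were lower and 0 higher, with a median log2 fold change of -3.69, or -2.35 and -2.27 under the 2 normexp scalings (-3.81 and -3.41 on the slides; adjusted p = 8.12e-08, and adjusted p = 0.0393 with an estimated correlation); 6 of them also stand on the fixed lists. All 5 Nat8 acetyltransferases were lower with a median of -6.60 (adjusted p = 3.48e-07, and 0.0393 with an estimated correlation), among them Nat8f1 (-6.98 ± 0.39). Of 10 Akr1 aldo-keto reductases 8 were lower and 1 higher, with a median of -2.59, or -1.37 and -1.38 under the 2 normexp scalings (adjusted p = 2.05e-05, and 0.0393 with an estimated correlation): Akr1c13 fell by 7.12 ± 0.18 while Akr1b1, aldose reductase, rose by 2.57 ± 0.40. Of 17 glutathione transferases 9 were lower and 0 higher, with a median of -1.47, or -0.83 without scaling (adjusted p = 2.42e-05, and 0.0429 with an estimated correlation), Gsta1 by -7.37 ± 0.34. Of 5 Ugt glucuronosyltransferases 3 were lower, with a median of -2.38 (adjusted p = 0.000431, and 0.0393 with an estimated correlation). Passing only with the preset correlation were Cyp (15 of 49 lower, 3 higher, 31 not called, median -0.39, turning to 0.24 with normexp and the 75th percentile and 0.25 without scaling, adjusted p = 0.00745, and 0.124 with an estimated correlation) and Slco (5 of 11 lower, 2 higher, median -1.44, and -0.19 with normexp and the 75th percentile, adjusted p = 0.0297, and 0.173). The same held for Aldh (9 of 16 lower, 2 higher, median -1.56, and -0.92 without scaling, adjusted p = 0.0156, and 0.0861), Sult (3 of 6 lower, 0 higher, median -2.41, adjusted p = 0.00350, and 0.0641) and Ces (7 of 11 lower, 1 higher, median -2.38, and -0.52 with normexp and the 75th percentile, adjusted p = 0.00105, and 0.0861). Members of these families are close in sequence, so a probe can also bind a relative's transcript, and their single values are uncertain.

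Calcium-binding families rose. Of 10 S100a genes 7 were higher and 0 lower, with a median of 2.82, or 1.42 and 1.24 under the 2 normexp scalings (adjusted p = 5.24e-05, and 0.0393 with an estimated correlation), S100a6 by 6.30 ± 0.36; 3 of them also stand on the fixed lists. Of 9 annexins 7 were higher and 1 lower, with a median of 3.69 (adjusted p = 0.000650, and 0.0393 with an estimated correlation): Anxa1 rose by 5.55 ± 0.28, and Anxa13 fell by 7.10 ± 0.84 with 1 allopurinol array well above background, a call lost with normexp and the 75th percentile (adjusted p = 0.0925). Of the annexins 1 also stands on the fixed lists. Of 162 Zfp zinc finger genes, 1 of them on the fixed lists, 26 were higher and 2 lower, with a median of 0.68, or 0.19 with normexp and quantile normalization and 1.31 without scaling (adjusted p = 0.000261, and 0.0393 with an estimated correlation). Of 84 ribosomal protein genes 33 were higher and 1 lower, with a median of 0.60, or 1.23 without scaling (adjusted p = 2.06e-08, but 0.349 with an estimated correlation).

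Dynlrb2, a dynein light chain, and Dnajb13, a radial spoke protein of cilia, were at least 66.4-fold and at least 50.7-fold higher, with no control array well above background. The hypothesis that motile cilia genes were higher as a group was tested on 22 other such genes, of which 4 were higher and 0 lower with a median of 1.07, or 0.19 with normexp and quantile normalization and 1.73 without scaling. They passed with the preset correlation (adjusted p = 0.0308) and not with an estimated one (adjusted p = 0.173), so the test leaves it open. Foxj1, the regulator of motile cilia, was at least 3.95-fold higher, and Enkur at least 6.18-fold. The call of Foxj1 was lost with the floor at 0.02 (adjusted p = 0.0898) and with normexp under either scaling (adjusted p = 0.291 and 0.0824), and that of Enkur with normexp and the 75th percentile (adjusted p = 0.333).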
